A study of Homo sapiens with 18 samples.

How the data were processed

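PolyA-selected RNA from 18 samples in 6 groups of 3 was sequenced in paired ends, per the labels' protocols. The groups were formed from the sample titles, which give the cell line, the hairpin and the replicate number. The submitters' processing notes name STAR, StringTie and the genome build GRCh38, with no versions. How these were run is not given in the sources used here.

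The 1 deposited table holds 78691 gene rows, each named by a gene identifier and a gene name, and 18 columns of values. Of these values, 0 were written as anything but a whole number of at least 0, the form of gene counts, and nothing in the labels states the unit of the deposited values. The 18 column names were compared with each sample's title, description, source name and characteristics after removal of punctuation and case, and 18 of them matched none. Columns were not assigned by their order or by their values. A first look at the table scaled the columns to CPM and kept genes above a low mean level. It compared the mean of the columns whose names begin with S with the mean of those beginning with T. It also read the levels of HCFC2 and of some colon epithelial genes. The report describes what that look showed in words, with no numerical value, and no column was assigned from it. All 18 columns were then left out of the analysis, so no test of expression was run, and other settings were tried only for the match of column names. Gene lists, tests, the rule for named genes and alternative settings had been fixed before the data were examined and remain unused. Python 3.11.15 was used to compare the names, count the rows and check that the values were whole numbers. The first look was not part of these steps.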

Results

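The study addressed the effect of lowering HCFC2, the gene of host cell factor 2, on gene expression in colorectal cancer cells. Per the labels, RNA sequencing covered 18 samples from SW620 and T84, both established human colorectal cancer cell lines. Each line had 3 conditions with 3 replicates each. The control cells received a lentivirus with a non-targeting short hairpin RNA. The other cells received a lentivirus with 1 of 2 short hairpin RNAs against HCFC2, numbered 287 and 449. The sample titles write the target as HCF2, and the series title and design text name it as HCFC2, which is used here. The labels call the replicates biological.

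The design implies comparisons of each hairpin with the control in each line, of the hairpins with each other, and of the hairpin effects between the lines. None of these comparisons was made here. The deposited table has 18 columns of values, named S1 to S9 and T10 to T18, and none of the 18 names matches a label of a sample. The letters are the initials of SW620 and T84 and the columns are as many as the samples, so the order in which the samples are listed would give a full assignment, which was not used. In a first look at the values, the means of the S and T columns were nearly alike, with few expressed genes far apart between them. Sets of columns that each mixed both lines would also have like means. This comparison therefore cannot tell whether the columns come from a single line. CEACAM5, KRT20, CDH17 and GUCY2C, genes known from colon epithelium, were low in the T columns. Their levels in the S columns are not given here, so the reading does not set the S and T columns apart. In the same look HCFC2 was highest in S1 to S3 and T10 to T12, the positions that the listed order would give to the controls. These readings are descriptions of unassigned columns and were not tested. Whether the letters stand for the lines, and whether the table holds both lines as labelled or a single line, was left open. Which columns hold control libraries would have had to be taken from the order of the columns or from the level of HCFC2 itself. Hairpins 287 and 449 both target HCFC2, so its level does not by itself tell them apart, and only the order would remain. Neither the order nor the level was used. Apart from that description, no measured level, fold change or test is therefore given for HCFC2 or for any other gene, and the depth of each sample is not given.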

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

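No paired analysis was possible because the column names carry no replicate number that ties them to a sample. An assignment by listed order would have given replicate numbers, and it was left unused by choice. The sample titles number the replicates within each group and do not state that equal numbers are paired across groups. Whether the design was paired is therefore not known here. Since no column was assigned to a group, none of the settings fixed for the tests was run. The 1 result that could be computed another way was the match of column names to samples, under rules chosen after seeing the data. All 18 columns matched no single sample with exact spelling, and also when a name only had to be held anywhere in a label. Under both rules, a name that fitted several samples would also be counted as matching no single sample.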
